A study of Homo sapiens with 3 samples.

How the data were processed

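Single cells were profiled by droplet RNA sequencing together with antibody tags, in 3 libraries. The tumour-cell library pooled EGFP-sorted cells of the recurrent glioblastoma line JX14P-RT grown in 3 humanized mice (mice 1, 2 and 3) and 2 naive mice (mice 4 and 5). A humanized mouse here is an immunodeficient NOG-EXL mouse that carries a human blood system grown from CD34+ haematopoietic stem cells, and a naive mouse lacks it. The other libraries held the human immune cells of mice 1, 2 and 3, from the tumour and from the blood. Tumour cells and tumour-infiltrating CD45+ cells were taken with a cell sorter, and blood CD45+ cells with a magnetic mouse/human chimera kit, per the labels' protocols. Samples had over 90% viable cells, and humanized and naive mice were harvested and processed in parallel on the same day, per the labels' protocols.

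The deposited values are counts of unique molecular identifiers (UMIs) per gene or antibody and per cell barcode, not normalized, in the 10x 3' gene expression and feature barcode format. The matrices were written by Cell Ranger 7.1.0, per the file headers, and the submitters' processing notes name Cell Ranger 6.1. The same notes name the builds GRCh38 and hg38, and the gene annotation behind the counts is not given in the sources used here. Whether the counting used introns or strand is likewise not given in the sources used here. The files hold 36601 genes, of which 34616 were matched by Ensembl identifier to GENCODE 29 on GRCh38, the source of the coordinates printed. They also hold 47 antibody features, 8 of them hashtags (antibodies that mark the mouse of origin) and 39 against surface proteins.

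The tumour-cell library held 12680 barcodes, 119684753 gene UMIs and a median of 8455.5 UMIs per barcode. The tumour-infiltrating library held 10688 barcodes, 62573310 gene UMIs and a median of 5040, and the blood library held 8724 barcodes, 61858457 gene UMIs and a median of 6097.5. Protein antibodies gave 1397802, 5421637 and 5878255 UMIs in the same order. Per the labels' protocols about 20000 cells were loaded for capture and about 5000 reads were sequenced per cell. The barcodes lie below the first of these numbers, and the median UMI counts lie above the second in each library, although a UMI needs at least 1 read.

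Barcodes with under 200 genes or over 20% mitochondrial UMIs were left out, 390 of the tumour-cell library, 40 of the tumour-infiltrating library and 186 of the blood library. Mice were assigned from the deposited hashtag map with Seurat 5.3.0 (HTODemux, quantile 0.99) in R 4.3.3. This left 9428, 9574 and 7292 single-mouse cells that passed the filters. Hashtags marked 1319, 477 and 441 barcodes as holding cells of different mice, and these were removed, as were 1607, 607 and 890 without a call. From these numbers, 4.09%, 2.55% and 3.54% of the single-mouse barcodes were estimated to hold a pair of cells of the same mouse. Scrublet marked only 0, 3 and 3 barcodes, so that this caller did not work here and such pairs remain in the data.

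Cells were clustered with scanpy 1.11.5 in Python 3.11.15 (counts scaled to 10000 per cell, log scale, 2000 variable genes without T cell receptor and immunoglobulin genes, 30 principal components, 15 neighbours, Leiden resolution 1). The immune libraries were clustered together without batch correction and the tumour-cell library alone. Clusters took a name only from fixed markers, and cluster numbers below refer to these clusterings. The test statistics, samples, covariates, gene lists, markers, filters and the rule for named genes were fixed before the data were examined. Chosen after seeing the data were the naming score (a marker counted as detected in at least 0.25 of a cluster's cells, clusters of at least 10 cells), the antibody thresholds and the decision to leave a blood-rich cytotoxic cluster unnamed. T-like cells with at least 20 CD4 antibody UMIs, and more of these than of CD8, were called CD4 T cells. Those with fewer than 20, and more CD8 than CD4 antibody UMIs, were called CD8 T cells, and 435 tumour-infiltrating and 175 blood T-like cells fell in neither. CD4 antibody counts within 2-fold of that threshold were seen in 399 tumour-infiltrating T-like cells (4.57%) and 209 in blood (3.92%). Monocyte or macrophage-like and conventional dendritic-like clusters formed the myeloid-like class.

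The mouse was the replicate. Counts were summed per mouse, tissue and cell class (at least 20 cells) and tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr, Benjamini-Hochberg adjustment, threshold 0.05). Tumour cells of humanized and naive mice were compared without a block. Tumour-infiltrating and blood cells were compared with the mouse as a block, because the hashtag map ties both tissues to the same animals. In T-like cells the deviations of same-mouse sums from their tissue means correlated across 12820 genes at 0.212, 0.324 and −0.0818, and in myeloid-like cells across 5936 genes at −0.214, 0.224 and −0.205. Between different mice these values ranged from −0.401 to 0.240 in T-like and from −0.390 to 0.411 in myeloid-like cells. The correlations therefore do not settle the pairing. Tissue and library are the same split, so that a library batch and the tissue cannot be told apart in any blood comparison. All adjusted p values for genes and surface proteins come from edgeR unless another tool is named. Levels are CPM values of the summed counts, mean ± SD over mice.

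Lists of genes were tested with limma 3.58.1's camera (preset correlation 0.01, then an estimated one) and with fry, which tests whether a list moves on balance in one direction. Surface proteins were tested on summed antibody counts in the same way as genes, and cell shares with two-sided exact permutation tests. With 3 pairs such a test cannot give a p under 0.25, and with 3 against 2 or 3 against 3 mice not under 0.1. Genes with 0 counts in a group are given as at least N-fold against a floor of 3 counts over that group, and genes with 1 to 3 counts as a ratio of totals with an exact 95% interval, both covering counting error only.

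The rule for named genes took the 10 largest rises and falls past the threshold with a mean log2 CPM of at least 5 and the same direction in every mouse or pair. It left out genes tied to sex, mitochondrial, ribosomal, immunoglobulin and T cell receptor segments and clone-based names. It added up to 4 members of each list past the threshold (2 where none passed) and a fixed set of checkpoint, antigen presentation and myeloid genes. Only part of these genes is printed, and that part was picked after their values were seen. In all, 103 sex-linked genes were left out of the summed counts and of every result.

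The script for the tests was tested on simulated counts with 200 changed genes. Of genes changed 4-fold it recovered 83.9% in the tumour-cell design (18004 genes tested), 98.4% in T-like cells (16185), 95.2% in CD8 T cells (11046), 98.4% in CD4 T cells (15325), 91.7% in myeloid-like cells (10196) and 73.8% for the difference between CD8 and CD4 T cells (13331). For 2-fold changes the shares were 15.6%, 40.3%, 40.3%, 25.4%, 27.7% and 6.15%, and for 1.5-fold changes 3.17%, 4.48%, 4.69%, 0%, 7.69% and 0%. False calls were 3.03%, 2.11%, 4.40%, 4.94%, 0% and 3.70% of all calls. The simulated spread between mice was an assumed value, not estimated from these data, and all sums shared 1 mean profile. These shares therefore check the script and are not the power or error of the real comparisons.

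Alternatives were RLE scaling, DESeq2 1.42.0, no filter on low counts, each mouse left out, sums thinned to the smallest total, a stricter hashtag rule (3 times the next and at least 10 UMIs), under 10% mitochondrial UMIs, Leiden resolution 0.5, no mouse block, and subsets of cells. Others were added after seeing the data, among them tumour cells only from clusters with at least 20 cells in every mouse, tumour cells outside a hypoxia-led cluster, all sorted cells, CD4 and CD8 T cells split by their UMIs, and monocyte or macrophage-like cells alone. Antibody counts alone (CD3 of at least 16 or CD14 of at least 10 UMIs) gave another set of shares. RLE scaling and DESeq2 shifted the log2 fold changes of all genes by a median of at most 0.0750 (DESeq2, CD4 T cells). Sequences of mouse origin were not analysed here.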

Results

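Glioblastoma cells of the recurrent line JX14P-RT, which carry an EGFP tag, were profiled after growth in mice with a human immune system and in mice without it. The human immune cells of the same humanized animals were profiled in the tumour and in the blood. RNA and surface antibody counts came from the same cells. After filtering and assignment to mice, the tumour-cell library held 718, 1215 and 2527 cells of humanized mice 1, 2 and 3 and 2440 and 2528 cells of naive mice 4 and 5. The tumour-infiltrating library held 2597, 3656 and 3321 cells of mice 1, 2 and 3, and the blood library held 3588, 2150 and 1554. Sums over glioma-like cells ranged from 3416780 to 24268518 UMIs in humanized and from 26110738 to 29604456 UMIs in naive mice. Sums over T-like cells ranged from 13448598 to 17523538 UMIs in the tumour and from 4434241 to 23322930 UMIs in blood. The myeloid-like sums were the smallest of the main classes, with 65 to 292 cells and 762719 to 2398174 UMIs per mouse in the tumour and 54 to 187 cells and 456659 to 3024531 UMIs in blood.

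The tumour-cell comparison asks how glioblastoma cells differ between a host with and a host without human immune cells. In humanized mice the tumour cells showed higher interferon-stimulated genes and lower hypoxia genes than in naive mice. With an estimated correlation no list kept its call (adjusted p of at least 0.1503). IFI27, an interferon-induced mitochondrial membrane protein, rose 19.5-fold (423 ± 222 CPM, n = 3, against 21.7 ± 0.274, n = 2; adjusted p = 0.00435). IFI44L rose 13.4-fold (68.4 ± 18.7 against 5.11 ± 0.503 CPM; adjusted p = 0.00206). POSTN, which encodes the matrix protein periostin, rose 4.03-fold (727 ± 134 against 181 ± 1.27 CPM; adjusted p = 0.00435). VEGFA, the main growth factor for blood vessels and a target of the hypoxia response, was 4.78-fold lower (32.1 ± 3.32 against 155 ± 73.9 CPM; adjusted p = 0.00719). BNIP3, a hypoxia-induced mitophagy receptor, was 3.55-fold lower (77.2 ± 3.74 against 275 ± 116 CPM; adjusted p = 0.00887). In clusters that every mouse filled with at least 20 cells these falls were smaller, with VEGFA at a log2 fold change of −1.31 and BNIP3 at −0.99, against −2.26 and −1.83 in all glioma-like cells. In total 378 of 18302 genes passed the threshold, 239 higher and 139 lower in humanized mice. This balance turned to 254 higher and 406 lower in clusters that every mouse filled, and all sorted singlets gave 865 higher and 244 lower. Other large changes among genes with a mean log2 CPM of at least 5 were RTN1 (log2 fold change 2.18), PARD3B (1.91), NCALD (−1.73), MGLL (−1.65), IGFBP5 (−1.44), NTRK3 (−1.41) and ID2 (−1.21). IGFBP5 (−0.54, adjusted p = 0.303) and ID2 (−0.62, adjusted p = 0.139) did not pass in clusters that every mouse filled.

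On GRCh38, IFI27 (ENSG00000165949) lies on chromosome 14 from 94104836 to 94116698 and IFI44L (ENSG00000137959) on chromosome 1 from 78619922 to 78646145. POSTN (ENSG00000133110) lies on chromosome 13 from 37562583 to 37598844, VEGFA (ENSG00000112715) on chromosome 6 from 43770184 to 43786487 and BNIP3 (ENSG00000176171) on chromosome 10 from 131966455 to 131982013. All are annotated as protein-coding genes, and the counts are per gene and do not tell its transcripts apart.

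**Figure D1:**
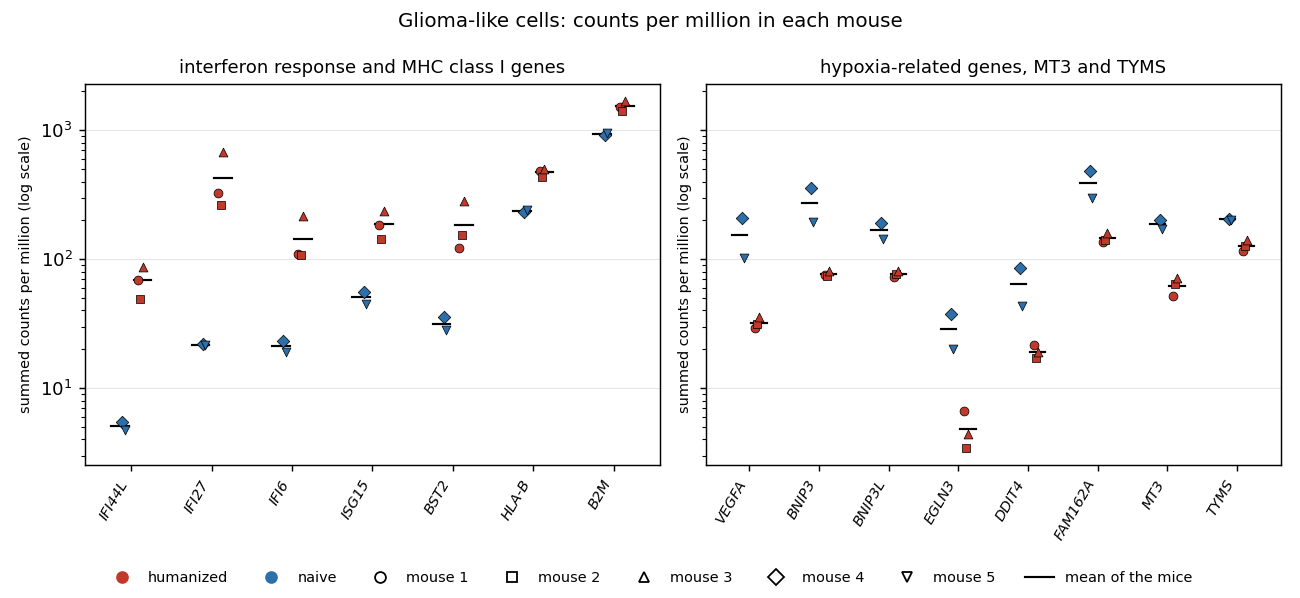
Levels of 15 genes in glioma-like cells, in CPM of the summed counts on a log scale, with points for mice and lines for the means of the humanized (n = 3) and naive (n = 2) mice. Interferon and antigen presentation genes are on the left, from IFI44L at 68.4 against 5.11 CPM to B2M, which did not pass the test, and on the right hypoxia and other genes that fell, such as VEGFA at 32.1 against 155 CPM.

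Of 22 measured genes of the type I interferon response list, 16 rose and 0 fell over all genes tested, and 21 rose and 0 fell when adjusted over the list alone, with a median log2 fold change of 2.79. EPSTI1 (log2 fold change 4.56), OAS1 (3.25), IFI6 (2.78), ISG15 (1.89) and XAF1 (1.86) were among them, and BST2 (2.56) and the transcription factor IRF9 (2.20), outside the list, rose as well. In clusters that every mouse filled with at least 20 cells, 15 of 20 list members rose with a median of 2.13, and IFI27 stood at 4.33 and IFI44L at 3.75. Camera gave the list in all glioma-like cells an adjusted p = 1.66e-59, and adjusted p = 0.1503 with an estimated correlation. Of 17 interferon gamma response genes, 4 rose and 14 did so when adjusted over the list alone, with GBP1 at 1.70, PARP14 at 1.08 and ICAM1, an adhesion molecule for leukocytes, at 1.52 (camera adjusted p = 2.13e-16, and adjusted p = 0.1503 with an estimated correlation). Of 15 genes of MHC class I presentation, 3 rose and 6 did so when adjusted over the list alone. These were led by HLA-B (472 ± 31.1 against 234 ± 5.91 CPM), HLA-C (295 ± 35.8 against 148 ± 3.10 CPM) and the peptide transporter gene TAP1 (log2 fold change 1.02), and camera gave adjusted p = 5.76e-08, and adjusted p = 0.219 with an estimated correlation. Without mouse 2 or without mouse 4, 0 of these genes passed, and without mouse 5 only 1 did. HLA-B and HLA-C are near-identical in parts, so that reads can be split between them. B2M, the shared light chain of class I molecules, stood at 1533 ± 144 against 939 ± 21.6 CPM and did not pass the test (adjusted p = 0.0912), although DESeq2 gave it an adjusted p = 0.000258.

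Hypoxia and glycolysis genes fell. Of 29 measured members, 14 fell and 0 rose over all genes, and 26 fell when adjusted over the list alone, with a median log2 fold change of −0.94 (camera adjusted p = 1.07e-31, and adjusted p = 0.219 with an estimated correlation). EGLN3, an oxygen sensor, was at −2.66, BNIP3L at −1.13 and VEGFA at −2.26, and the stress gene DDIT4 (−1.77) and FAM162A (−1.42), outside the list, fell with them. Most humanized cells lay in clusters 11, 12 and 0 (52.1%) and most naive cells in clusters 2, 6 and 7 (50.1%). Cluster 7, led by hypoxia genes, took 534 of its 658 cells from mouse 4, and outside it the list's median was −0.81 with 13 members lower. The number of lower members, 14 of 29 with all mice, was 2 without mouse 1, 3 without mouse 2, 4 without mouse 3, 7 without mouse 4 and 19 without mouse 5. Without mouse 4 the median was −0.62, and in clusters that every mouse filled with at least 20 cells it was −0.58 with 6 of 27 lower. In these shared clusters BNIP3L stood at −0.54 and did not pass (adjusted p = 0.0896), and DDIT4 was at −0.83, FAM162A at −0.77 and EGLN3 at −1.95.

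Of 38 proliferation genes 0 rose and 2 fell, TYMS (127 ± 11.7 against 203 ± 1.84 CPM) and the replication licensing gene MCM3 (29.1 ± 2.79 against 50.2 ± 6.95 CPM), and 16 fell when adjusted over the list alone (median −0.31, camera adjusted p = 5.76e-08, and adjusted p = 0.264 with an estimated correlation). In clusters that every mouse filled with at least 20 cells, 25 proliferation genes fell and their median was −0.9996. Of 25 astrocyte-like state genes 1 fell, the metallothionein gene MT3 (−1.58), and 6 when adjusted over the list alone (camera adjusted p = 0.000248, and adjusted p = 0.424 with an estimated correlation). Of 25 neural progenitor-like state genes 1 rose, DCX, a microtubule protein of migrating neuroblasts (8.06 ± 3.38 against 0.663 ± 0.00817 CPM), and when adjusted over the list alone 6 rose and 2 fell (camera adjusted p = 0.00438, and adjusted p = 0.264 with an estimated correlation). This list turned in clusters that every mouse filled, where 0 of 18 members rose, 3 fell and the median was −0.26, against 0.45 in all glioma-like cells. DCX and SNTG1 (log2 fold change 4.28) were leading genes of cluster 8, which took 105 of its 127 cells from mouse 3, and SNTG1 no longer passed in clusters that every mouse filled (1.499, adjusted p = 0.327).

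The other lists did not pass camera's test. Extracellular matrix and mesenchymal transition genes had 2 of 28 members higher (4 adjusted over the list alone, camera adjusted p = 0.0556), POSTN and TNC, the latter for the matrix protein tenascin C (59.6 ± 6.79 against 16.4 ± 5.78 CPM). Mesenchymal state genes had 3 of 28 higher and 1 lower (7 and 1 adjusted over the list alone, adjusted p = 0.0876). The lower gene was GSN, which encodes the actin-severing protein gelsolin (−1.12), and in clusters that every mouse filled it stood at −0.14 (adjusted p = 0.787). The higher genes were SPP1 at 15.3 ± 0.768 against 1.97 ± 1.39 CPM, CHI3L1 at 25.8 ± 11.6 against 6.12 ± 0.935 CPM and IFITM3, also an interferon target, at a log2 fold change of 1.37. Immune checkpoint and suppressive factors had 1 of 15 higher, LGALS9 (1.77), with 4 higher and 1 lower adjusted over the list alone (adjusted p = 0.108). CD276 stood at 0.39 (adjusted p = 0.226). Chemokines and myeloid growth factors had only VEGFA lower among 12 measured, also when adjusted over the list alone (adjusted p = 0.637). TNF response genes had only ICAM1 higher among 16 under both adjustments (adjusted p = 0.503). Among 20 immediate early and heat shock genes 1 was higher, HSPA1A, with 57 against 3 UMIs and a ratio of 26.7 (95% interval 8.68 to 133). This gene shares sequence with its copy HSPA1B, and with the list alone 1 rose and 1 fell (adjusted p = 0.222). Unfolded protein response genes had 0 of 18 changed under both adjustments (adjusted p = 0.0511), with HSP90B1 at 0.34 and HSPA5 at 0.47. Oligodendrocyte progenitor-like genes had 0 of 22 changed under both adjustments (adjusted p = 0.0556), with OLIG1 at −0.78 and LHFPL3 at −1.04. MHC class II had 3 genes measured and 0 changed, with 1 higher adjusted over the list alone (adjusted p = 0.177), CTSS at 1.12 and HLA-DMA at −0.16. CD274, CD74 and HLA-DRA were too low to be tested.

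Glioma-like cells of mice 1, 2 and 3 had medians of 5626, 9440 and 11223 UMIs and 7.76%, 5.49% and 4.72% mitochondrial UMIs, against 10797.5 and 12027 UMIs and 5.22% and 4.84% in mice 4 and 5. An unnamed cluster with low UMI counts, led by IFITM3 and kept out of the glioma-like class, held 11.3% ± 9.10 of the cells of humanized and 1.78% ± 0.443 of those of naive mice. Leaving out mice moved the count of 378 genes: to 133 without mouse 1, 88 without mouse 2, 237 without mouse 3 and 653 without mouse 4, the lone remaining naive sample being assumed to vary like the others. Of the 41 named tumour-cell genes that passed, 22 did not pass in at least 1 fit without a mouse, 15 without mouse 1 and 18 without mouse 2. Among them were VEGFA and BNIP3 without mouse 1 (adjusted p = 0.0548 and 0.0563), and HLA-B, HLA-C, TAP1, ICAM1, GBP1, PARP14, LGALS9, TYMS and MCM3 without mouse 2. Fry called 0 of the 16 lists, with a smallest adjusted p = 0.0515. Of 12 surface antibodies tested on the same cells, 0 passed edgeR's threshold and 1 had an unadjusted p under 0.05 (CD25). CD25 had at most 0.0358 UMIs per cell, and humanized mouse 3 lay below naive mouse 4. HLA-ABC, the class I protein, averaged 151, 106 and 89.3 antibody UMIs per cell in the humanized and 36.7 and 42.1 in the naive mice (log2 fold change 1.25, SE 0.63, adjusted p = 0.321), while limma on centred log ratios called this antibody alone (difference 0.73, adjusted p = 0.00115).

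The cell composition of tumour and blood was compared next, with different isolation methods for the tissues, which can set shares. T-like cells made up 91.6% ± 4.13 of tumour-infiltrating and 73.5% ± 3.56 of blood cells (n = 3 mice), a difference of 18.1 points that was present in 3 of 3 mice (exact paired permutation p = 0.25, the smallest possible). With classes by antibody counts alone this difference was 9.14 points. B-like cells made up 0.214% ± 0.130 in the tumour and 9.81% ± 3.85 in blood, lower in the tumour in 3 of 3 mice (exact paired permutation p = 0.25). Myeloid-like cells made up 5.21% ± 3.23 and 4.68% ± 1.04, higher in the tumour in 1 of 3 mice (exact paired permutation p = 1), and the difference of 0.536 points turned to −1.85 without mouse 3. By antibody counts alone they made up 2.58% ± 1.07 and 1.28% ± 0.502, higher in the tumour in 3 of 3 mice (difference 1.30 points, exact paired permutation p = 0.25). Within the myeloid class, monocyte or macrophage-like cells were 4.66% ± 2.50 in the tumour and 2.86% ± 0.947 in blood, and conventional dendritic-like cells 0.553% ± 0.734 and 1.82% ± 0.799. NK-like cells were 0.145% ± 0.104 and 1.25% ± 0.787, mast or basophil-like cells 2.06% ± 2.43 and 1.10% ± 0.965, and plasmacytoid dendritic-like cells 0.158% ± 0.0830 of blood cells. The cytotoxic cluster left unnamed held 0.666% ± 0.297 of tumour and 8.07% ± 5.95 of blood cells, and with it among the T-like cells their difference was 10.7 points.

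**Figure D2:**
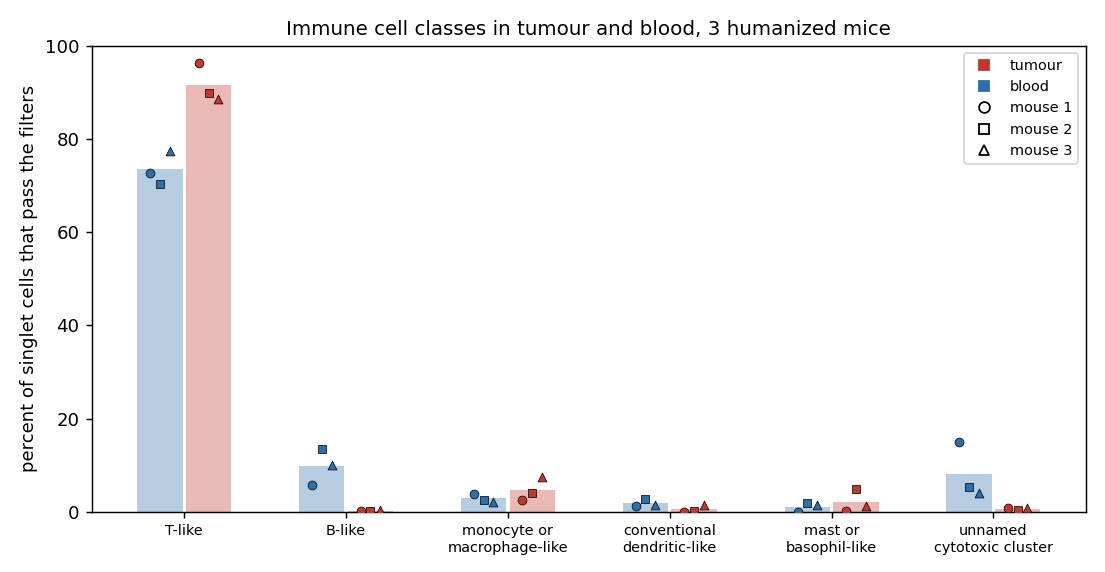
Share of cells per class, in percent of all single-mouse cells of a library, with bars for the mean of 3 mice and points for the mice. T-like cells averaged 91.6% in the tumour and 73.5% in blood, B-like cells 0.214% and 9.81%.

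T-like cells of the tumour were compared with those of the blood of the same mice, a comparison of infiltrating with circulating T cells. In the tumour they had higher activation, residency, effector and checkpoint genes and lower genes of naive and central memory cells. With an estimated correlation none of these lists kept its call (adjusted p from 0.0749 to 0.227). RGS1, a regulator of G protein signalling that limits migration to chemokines, was 346-fold higher (899 ± 57.1 against 2.62 ± 1.03 CPM, n = 3 pairs, adjusted p = 0.00186). CD69, which retains lymphocytes in tissue, stood at 826 ± 165 against 36.5 ± 11.9 CPM (adjusted p = 0.00199). The checkpoint receptor gene CTLA4 rose 20.005-fold (290.2 ± 134 against 13.6 ± 4.55 CPM, adjusted p = 0.00547). GZMB, the cytotoxic protease granzyme B, rose 16.5-fold (208 ± 215 against 11.2 ± 9.38 CPM, adjusted p = 0.00211). The GZMB rise was smaller with the unnamed cytotoxic cluster among the T-like cells, as given below. LEF1, a transcription factor of naive T cells, was 13.5-fold lower (56.6 ± 16.8 against 767 ± 231 CPM, adjusted p = 0.00203). In total 4849 of 16151 genes passed, 2141 higher and 2708 lower in the tumour, and DESeq2 gave 2749 higher and 2163 lower.

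RGS1 (ENSG00000090104) lies on chromosome 1 from 192575727 to 192580031 of GRCh38, CTLA4 (ENSG00000163599) on chromosome 2 from 203867771 to 203873965, GZMB (ENSG00000100453) on chromosome 14 from 24630954 to 24634267 and LEF1 (ENSG00000138795) on chromosome 4 from 108047545 to 108168956, all protein-coding. Most tumour T-like cells lay in clusters 5, 1 and 10 (58.6%) and most blood T-like cells in clusters 19 and 7 (54.1%). Their median mitochondrial shares were 1.39% to 1.71% in the tumour and 2.29% to 5.26% in blood.

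**Figure D3:**
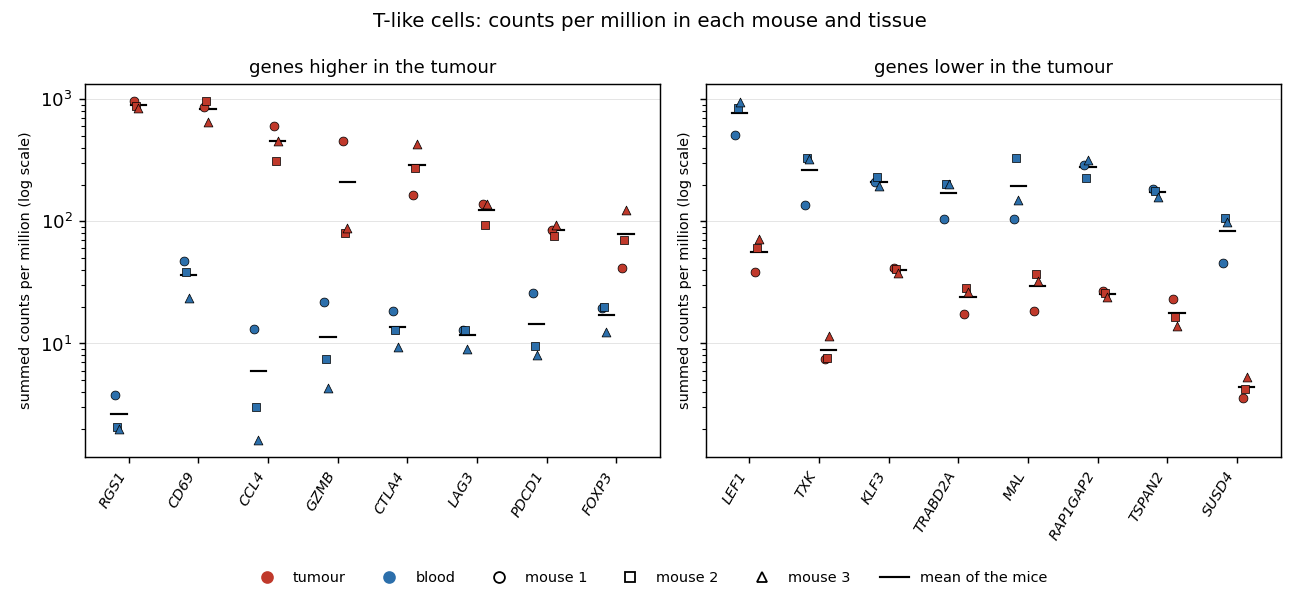
Levels of 16 genes in T-like cells of tumour and blood, in CPM of the summed counts on a log scale, with points for the 3 mice and lines for the means. Genes higher in the tumour are on the left, such as RGS1 at 899 against 2.62 CPM, and genes lower in the tumour are on the right, such as LEF1 at 56.6 against 767 CPM.

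Of 20 T cell activation and costimulation genes, 15 rose and 1 fell (16 and 1 adjusted over the list alone), with TNFRSF9, the costimulatory receptor 4-1BB, at a log2 fold change of 5.75 and CD83 at 2.99. Of 17 tissue residency genes 14 rose (15 adjusted over the list alone), among them ZNF683, the transcription factor Hobit, at 3.92. Of 21 cytotoxic effector genes 17 rose and 1 fell (18 and 2 adjusted over the list alone), with GZMH at 4.14, IFNG at 3.33 and CCL3 at 6.32. The T-like class leaves out the unnamed cytotoxic cluster, most of whose cells are from blood, a choice made after seeing the data that lowers effector genes in blood. With that cluster 15 cytotoxic effector genes rose and 2 fell, and their median went from 3.33 to 2.55, with GZMB at 2.81, GZMH at 2.55 and CCL3 at 4.96. Of 20 exhaustion and checkpoint genes 17 rose and 1 fell (17 and 2 adjusted over the list alone), and 15 rose and 1 fell with the cytotoxic cluster. LAG3 stood at 123 ± 26.0 against 11.6 ± 2.24 CPM, PDCD1, the receptor PD-1, at 84.7 ± 9.02 against 14.4 ± 9.88 CPM, HAVCR2 at a log2 fold change of 2.87, TIGIT at 3.04, LAYN at 4.9998 and ENTPD1 at 2.86. Of 18 regulatory T cell genes 13 rose (13 adjusted over the list alone), with FOXP3, the defining transcription factor, at 78.7 ± 41.995 against 17.2 ± 4.23 CPM and the suppressive cytokine gene IL10 at 5.62. The regulatory list shares IL2RA, TNFRSF4, TNFRSF18 and TNFRSF9 with the activation list and CTLA4, TIGIT, LAYN, ENTPD1 and BATF with the exhaustion list. The counts of these lists therefore overlap, here and below. Camera's adjusted p values were 5.07e-19, 7.78e-20, 5.07e-19, 1.97e-13 and 4.16e-11 for these lists, and with an estimated correlation the adjusted p values were 0.0749, 0.0749, 0.132, 0.0749 and 0.227.

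Stimulus-induced genes also rose. Of 20 immediate early and heat shock genes, which cells can also induce during isolation, 12 rose (16 adjusted over the list alone), with FOS at 277 ± 105 against 12.97 ± 5.17 CPM, JUN at 4.39 and DUSP1 at 4.03. NR4A1 is also in the activation and residency lists and EGR2 in the activation list, so that this limit reaches those lists too. Of 18 TNF and NF-kB response genes 14 rose and 0 fell (14 and 1 adjusted over the list alone), with TNFAIP3, a feedback inhibitor of NF-kB, at 3.93, CCL20 at 6.28 and RELB at 1.42. Of 18 unfolded protein response genes 10 rose (13 adjusted over the list alone), with SESN2 at 3.34, DNAJB9 at 2.32, HERPUD1 at 2.03 and DDIT3 at 2.16. Camera's adjusted p values were 2.12e-15, 7.62e-10 and 3.25e-05, and with an estimated correlation the adjusted p values were 0.0907, 0.0838 and 0.384. The orphan nuclear receptor genes NR4A3 (log2 fold change 8.61) and NR4A2 (5.82), the phosphatase gene DUSP2 (6.38), RGS2 (5.89), ZNF331 (5.51), PARD6G (6.105) and the chemokine genes CCL4 (6.59) and CCL4L2 (5.59), near-identical copies, were among the largest rises of genes with a mean log2 CPM of at least 5.

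Of 13 MHC class II genes 10 rose and 1 fell under both adjustments, with HLA-DQB1 and HLA-DMA each at 1.91. Of 15 MHC class I genes 2 rose under both adjustments, HLA-F (1.21) and PDIA3 (1.13). Of 22 type I interferon genes 5 rose (4 adjusted over the list alone), with OASL at 2.37, IFI44 at 1.35 and IRF7 at 1.46. Of 19 interferon gamma genes 5 rose and 2 fell under both adjustments, with SOCS1 at 3.79, GBP5 at 1.37 and IDO1 at −1.70. The 4 lists had camera adjusted p values of 2.06e-06, 0.0280, 0.000389 and 0.0429, and with an estimated correlation adjusted p values of 0.124, 0.512, 0.512 and 0.485. Naive and central memory genes fell, 11 of 18 and 0 higher (13 adjusted over the list alone, camera adjusted p = 4.25e-08, and adjusted p = 0.227 with an estimated correlation), with TRABD2A at −2.78, KLF3 at −2.40 and MAL at −2.62. Outside that list TXK, a Tec family kinase of T cells (8.85 ± 2.30 against 264 ± 111 CPM), PLXNA4 (−4.35), EDA (−4.33), SUSD4 (−4.18), RAP1GAP2 (−3.44), RNF144A (−3.33), TSPAN2 (−3.30) and PDLIM1 (−3.28) were among the largest falls at that level.

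Hypoxia and glycolysis genes had 3 of 25 higher and 2 lower (2 and 2 adjusted over the list alone) and proliferation genes 3 of 38 higher (1 adjusted over the list alone), with camera adjusted p values of 0.126 and 0.0905. SLC2A3, a glucose transporter gene, stood at 1.85, PFKFB3 at 1.30, PFKFB4 at −2.33, EGLN3 at −2.34 and the replication licensing gene MCM6 at 1.80. The haemoglobin gene HBB gave 10 UMIs in tumour T-like cells and 13052 in blood (log2 fold change −10.74). It was present in all 6 blood classes examined for it, from 33.2 CPM in conventional dendritic-like to 1124 CPM in monocyte or macrophage-like cells. Its falls, here and below, therefore need not be changes of the cells compared. Without mouse 1 the count of changed genes was 3039 and without mouse 2 it was 1129, and FOXP3, RELB, IFI44, IRF7, HLA-F, PDIA3, GBP5, IDO1, SLC2A3, PFKFB3 and PFKFB4 did not pass without mouse 2.

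On the surface of T-like cells 3 of 12 tested antibodies passed edgeR's threshold. CD8 antibody fell from 163, 197 and 118 UMIs per cell in blood to 18.8, 5.85 and 9.08 in the tumour of mice 1, 2 and 3 (log2 fold change −4.48, adjusted p = 0.00231), although the CD3 antibody did not pass (−0.03, adjusted p = 0.868). With scaling by library size only, CD3 passed (0.74, adjusted p = 0.0225) and CD4 did not (−0.07, adjusted p = 0.778). CD4 antibody stood at −0.83 (adjusted p = 0.0403) and CD15, a myeloid antigen with under 5 UMIs per cell here, at 1.68 (adjusted p = 0.0253). Only CD8 passed when any mouse was left out, and only CD8 passed without the mouse block. Class I protein (HLA-ABC) stood at −0.14 (adjusted p = 0.774).

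CD8 T cells of the tumour (1926 cells) and blood (743 cells), separated by antibody, were compared in the same way, for the cytotoxic lineage alone. The CD8 antibody signal was low in the tumour library. Of 3022 tumour T-like cells with CD8A or CD8B and no CD4 UMIs, 1759 lay in the CD8 gate, against 532 of 669 in blood. RGS1 stood at 947 ± 138 against 1.75 ± 0.624 CPM (adjusted p = 0.000495) and GZMB at 520.2 ± 315 against 63.0 ± 81.0 CPM (adjusted p = 0.00464). PDCD1 stood at 98.0 ± 35.5 against 8.26 ± 8.32 CPM (adjusted p = 0.00346), and LEF1 at 42.9 ± 28.4 against 1198 ± 281 CPM (adjusted p = 0.000921). CA6, a secreted carbonic anhydrase gene (ENSG00000131686, chromosome 1 from 8945867 to 8975092), had the largest fall apart from HBB among genes with a mean log2 CPM of at least 5 (log2 fold change −6.57). In total 2592 of 11177 genes passed, 1198 higher and 1394 lower, and DESeq2 gave 1131 higher and 845 lower. Most of these cells lay in cluster 5 in the tumour (61.2%) and in cluster 18 in blood (73.2%). With subsets split by CD4, CD8A and CD8B UMIs 2883 genes passed, 2358 of them shared with the antibody gate.

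In CD8 T cells 16 of 20 cytotoxic effector genes rose (16 rose and 1 fell adjusted over the list alone), with XCL1, a chemokine for cross-presenting dendritic cells, at a log2 fold change of 5.28, CST7 at 3.88 and IFNG at 3.05. The unnamed cytotoxic cluster of the blood was left out here too, and with it blood CD8 T cells numbered 695, 329 and 281 in mice 1, 2 and 3 against 261, 249 and 233 without it. With it 13 of 21 cytotoxic effector genes rose and 2 fell, and their median went from 3.18 to 2.19, with GZMB at 2.59, CST7 at 2.32 and IFNG at 2.35. Residency genes rose in 15 of 17 (15 adjusted over the list alone), with the chemokine receptor gene CXCR6 at 4.67, and activation genes in 13 of 19, with 1 lower (18 and 1 adjusted over the list alone). Exhaustion and checkpoint genes rose in 14 of 18 (16 rose and 2 fell adjusted over the list alone), with CTLA4 at 5.15, HAVCR2 at 3.48, LAG3 at 3.37 and TIGIT at 3.25. With the cytotoxic cluster 14 of 19 such genes rose and 2 fell, with a median of 2.25 against 3.425, and PDCD1 stood at 2.54, CTLA4 at 4.09, LAG3 at 2.25 and TIGIT at 2.10. Naive and central memory genes fell in 15 of 18 (15 adjusted over the list alone), with TRABD2A at −3.98, ACTN1 at −3.93 and KLF3 at −2.66. Camera's adjusted p values were 2.66e-14, 2.52e-17, 4.84e-16, 5.82e-14 and 1.08e-13, and with an estimated correlation the adjusted p values were 0.236, 0.216, 0.216, 0.236 and 0.238. MHC class II genes rose in 10 of 12 under both adjustments, with HLA-DMA at 2.09, HLA-DQA1 at 2.365 and HLA-DQB1 at 2.29, and immediate early genes in 12 of 18 (14 adjusted over the list alone). Regulatory T cell genes rose in 9 of 13 (11), TNF response genes in 7 of 12 (8) and unfolded protein response genes in 9 of 17 (12), the numbers in parentheses being those adjusted over the list alone. These lists had camera adjusted p values of 1.33e-08, 2.61e-12, 7.21e-08, 1.54e-05 and 5.28e-06, and with an estimated correlation adjusted p values of 0.236, 0.236, 0.236, 0.216 and 0.289. The regulatory list shares members with the activation and exhaustion lists, so that its rise in CD8 T cells is not separate from theirs.

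Type I interferon genes rose in 8 of 22 CD8 T cell members (10 adjusted over the list alone), with OASL at 3.27. Interferon gamma genes rose in 8 of 16 (9 rose and 1 fell adjusted over the list alone) and MHC class I genes in 4 of 14 under both adjustments. Camera's adjusted p values were 7.26e-05, 0.000375 and 0.0174, and with an estimated correlation the adjusted p values were 0.432, 0.326 and 0.432. Hypoxia genes (2 of 21 higher, 1 lower, the same numbers adjusted over the list alone, adjusted p = 0.221) and proliferation genes (1 of 36 higher, 0 adjusted over the list alone, adjusted p = 0.213) were not called. Other large changes at that level were NR4A3 (995 against 2 UMIs, ratio 266, 95% interval 73.5 to 2201), DUSP2 (6.28), RGS2 (6.21), DUSP4 (6.09), CCL4 (6.07), NR4A2 (5.89), PARD6G (5.86), TENT5C (5.53) and ZNF331 (5.41) on the higher side. On the lower side were TXK (−5.64), CR1 (−5.54), LEF1-AS1 (−5.42), which is antisense to LEF1, PLXNA4 (−4.90), SUSD4 (−4.70), PCSK5 (−4.69) and PELI2 (−4.44), with HBB at 3 against 1052 UMIs, a ratio of 655 (95% interval 224 to 3183). HBB was present in every blood class examined, so that its blood signal is not particular to CD8 T cells. The count was 1475 without mouse 1 and 1287 without mouse 2.

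CD4 T cells of the tumour (6368 cells) and blood (4409 cells) were compared in the same way. FOXP3 stood at 99.5 ± 44.9 against 20.3 ± 3.78 CPM (adjusted p = 0.010004), CTLA4 at a log2 fold change of 4.25 and IL10 (ENSG00000136634, chromosome 1 from 206767602 to 206772494) at 13.2 ± 8.52 against 0.125 ± 0.117 CPM. Of 18 regulatory T cell genes 14 rose (15 adjusted over the list alone, camera adjusted p = 5.10e-13, and adjusted p = 0.194 with an estimated correlation). Of 20 cytotoxic effector genes 17 rose and 1 fell (18 and 1 adjusted over the list alone), among them the chemokine gene CCL5 at 4.39 and GZMB at 4.45 (camera adjusted p = 4.58e-25, and adjusted p = 0.0792 with an estimated correlation). The antibody gate bears on this: 940 of the CD4-gated tumour cells and 67 of the CD4-gated blood cells had CD8A or CD8B and no CD4 UMIs. With subsets split by these UMIs GZMH, at 4.51 in the antibody gate, stood at 1.28 and did not pass (adjusted p = 0.0846). In that split 11 of 19 cytotoxic effector genes rose and 1 fell, with a median of 1.52 against 3.40, while 13 of 18 regulatory T cell genes rose. In total 4738 of 15299 genes passed, 2105 higher and 2633 lower, and DESeq2 gave 2581 higher and 1959 lower. Most of these cells lay in clusters 10 and 1 in the tumour (51.6%) and 19 and 7 in blood (61.5%).

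Residency genes rose in 15 of 17 CD4 T cell members (16 adjusted over the list alone), with CXCR6 at a log2 fold change of 5.74. Activation genes rose in 16 of 20 (16 rose and 1 fell adjusted over the list alone), with TNFRSF9 at 6.04. Exhaustion and checkpoint genes rose in 17 of 20 with 1 lower (17 and 2 adjusted over the list alone), with PDCD1 at 2.51, LAG3 at 3.25, TIGIT at 2.93 and HAVCR2 at 2.29. Immediate early genes rose in 13 of 20 (15 adjusted over the list alone), and TNF response genes in 13 of 17 (13 rose and 1 fell adjusted over the list alone), with CCL20 at 6.47. Naive and central memory genes fell in 11 of 18 (13 adjusted over the list alone), with TCF7, a transcription factor of naive and memory cells, at −2.39, KLF3 at −2.34 and TRABD2A at −2.56. Camera's adjusted p values were 2.90e-20, 2.15e-20, 7.68e-13, 3.99e-15, 1.24e-08 and 7.99e-07, and with an estimated correlation the adjusted p values were 0.0763, 0.0763, 0.0763, 0.0763, 0.0792 and 0.194. MHC class II genes rose in 10 of 13 with 1 lower under both adjustments, with HLA-DMA at 1.69 and HLA-DRA at 1.13. Unfolded protein response genes rose in 9 of 18 (13 adjusted over the list alone) and type I interferon genes in 6 of 22 under both adjustments. Their camera adjusted p values were 0.000156, 5.76e-05 and 0.000608, and with an estimated correlation adjusted p values were 0.262, 0.368 and 0.554.

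Not called in CD4 T cells were interferon gamma genes (4 of 18 higher and 3 lower, 5 and 3 adjusted over the list alone, adjusted p = 0.0778), MHC class I genes (2 of 14 higher and 1 lower, 2 and 0 adjusted over the list alone, adjusted p = 0.0663), hypoxia genes (3 of 24 higher and 2 lower under both adjustments, adjusted p = 0.0876) and proliferation genes (4 of 38 higher, 1 adjusted over the list alone, adjusted p = 0.0663). Among genes with a mean log2 CPM of at least 5 the largest rises included NR4A3 (8.59), RGS1 (8.32), CCL4 (6.50), DUSP2 (6.29), RGS2 (5.73), NR4A2 (5.67), ZNF331 (5.46) and METRNL (5.30). The largest falls included HBB (−11.30), TXK (−4.68), PLXNA4 (−4.40), SUSD4 (−4.27), EDA (−4.24), TSPAN18 (−3.70), LEF1 (−3.50), RAP1GAP2 (−3.36), MTSS1 (−3.32) and PDLIM1 (−3.30). The HBB signal of the blood was present in every class examined and is not particular to CD4 T cells. The count was 2124 without mouse 1, 1483 without mouse 2 and 7119 without mouse 3.

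Whether the tissue difference itself differed between CD8 and CD4 T cells was tested as an interaction. The mouse was an additive block, so that the CD8 and CD4 sums of a mouse and tissue entered as independent although they are paired. With edgeR 0 of 13785 genes passed, while 1218 had an unadjusted p under 0.05, DESeq2 called 160 (53 with a higher and 107 with a lower difference in CD8 T cells), and edgeR without a filter on low counts called 233. Camera called 3 of 15 lists. Naive and central memory genes fell more in CD8 T cells (median −2.67) than in CD4 T cells (median −1.49), with 0 higher and 4 lower differences adjusted over the list alone (camera adjusted p = 2.74e-11, and adjusted p = 0.489 with an estimated correlation). MHC class II genes rose more in CD8 T cells (median 2.11) than in CD4 T cells (1.31), with 2 members higher adjusted over the list alone (adjusted p = 5.69e-06, and adjusted p = 0.489 with an estimated correlation). Interferon gamma genes had a median of 1.03 in CD8 and 0.59 in CD4 T cells, with 1 member higher adjusted over the list alone (adjusted p = 0.0144, and adjusted p = 0.992 with an estimated correlation), and this call ended when a mouse was left out (adjusted p up to 0.116). Fry called 0 lists (smallest adjusted p = 0.279), and neither test called the other 12 lists (camera adjusted p from 0.360 to 0.997). Over all genes 0 members of any list had a different tissue difference. Adjusted over the list alone, activation genes and exhaustion genes each had 1 member higher and 1 lower in CD8 T cells, and the other 10 lists had 0. With the unnamed cytotoxic cluster the CD8 medians of naive, MHC class II and interferon gamma genes were −2.35, 1.70 and 0.91. In that setting the lists were not tested for the difference. With subsets split by UMIs these medians were −2.81, 2.03 and 1.04 in CD8 and −1.18, 1.10 and 0.46 in CD4 T cells. The antibody gate for CD4 T cells held 940 tumour and 67 blood cells with CD8A or CD8B and no CD4 UMIs.

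Myeloid-like cells of the tumour (516 cells) were compared with those of the blood (356 cells). The class joins monocyte or macrophage-like and conventional dendritic-like cells. The tumour cells had higher genes of tumour-associated macrophages, inflammatory cytokines and cell division, and lower FCN1 and CLEC9A. With an estimated correlation none of these lists kept its call (adjusted p from 0.0951 to 0.308). SPP1, which encodes the secreted glycoprotein osteopontin, had 3747 ± 2164 CPM in the tumour and 0 UMIs in blood, at least 6577-fold higher. C1QC, a chain of the first complement component, was 38.4-fold higher (977 ± 269 against 26.7 ± 16.2 CPM, adjusted p = 5.97e-06). IL1B, a pyrogenic cytokine, was 38.9-fold higher (1209.9 ± 336 against 32.4 ± 14.7 CPM, adjusted p = 6.21e-06). FCN1, a lectin of circulating monocytes, was 4.41-fold lower (97.2 ± 39.2 against 419.6 ± 116 CPM, adjusted p = 0.00255). CLEC9A, a receptor of cross-presenting dendritic cells, was 195-fold lower (4 against 906 UMIs). Conventional dendritic-like cells numbered 56 in the tumour, with 0 of mouse 1, and 128 in blood. Without them CLEC9A was too low to be tested, so that its fall may reflect the mix of cells. In total 2827 of 10100 genes passed, 1373 higher and 1454 lower, while RLE scaling gave 1441 higher and 1366 lower and DESeq2 1115 higher and 911 lower. Most monocyte or macrophage-like cells lay in cluster 13 in the tumour (60.4%) and all in cluster 20 in blood, while the dendritic-like cells lay in clusters 15 and 27. Cluster 13 had a median of 2175.5 UMIs and 0.176% mitochondrial UMIs, against 11886.5 and 3.39% in cluster 20, and it held 0 cells of mouse 1. Whether the cells of cluster 13 are human, or mouse cells whose reads matched the human reference, was not tested. This limit reaches the tumour myeloid-like values of mice 2 and 3. In the tumour of mice 1, 2 and 3 C1QC stood at 1179, 1079 and 672 CPM, and APOE at 82.1, 3228 and 1083 CPM, so that the size of the APOE rise differed with the presence of this cluster.

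SPP1 (ENSG00000118785) lies on chromosome 4 from 87975650 to 87983426 of GRCh38, C1QC (ENSG00000159189) on chromosome 1 from 22643630 to 22648110 and IL1B (ENSG00000125538) on chromosome 2 from 112829751 to 112836903. FCN1 (ENSG00000085265) lies on chromosome 9 from 134905890 to 134917963 and CLEC9A (ENSG00000197992) on chromosome 12 from 10030677 to 10066027, and all are protein-coding.

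**Figure D4:**
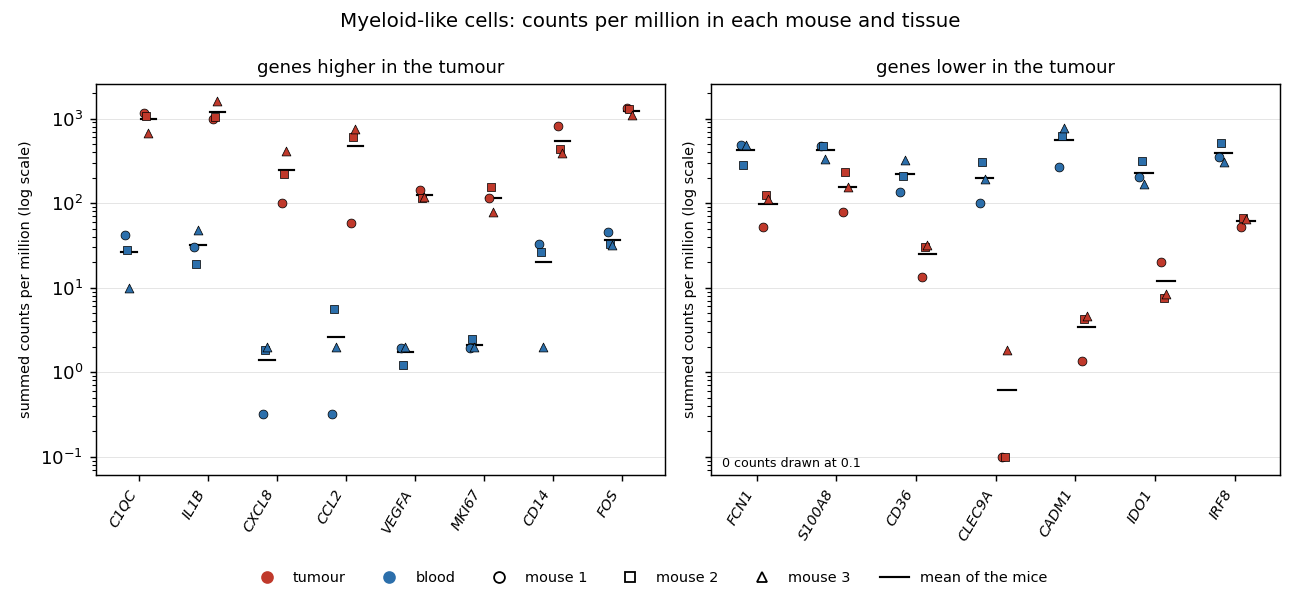
Levels of 15 genes in myeloid-like cells of tumour and blood, in CPM of the summed counts on a log scale, with points for the 3 mice, lines for the means and counts of 0 drawn at 0.1. Genes higher in the tumour are on the left, such as C1QC at 977 against 26.7 CPM, and genes lower in the tumour are on the right, such as FCN1 at 97.2 against 419.6 CPM.

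All 12 measured inflammatory cytokine genes rose, also when adjusted over the list alone, with CXCL8 at a log2 fold change of 7.36, CCL2 at 7.20, OSM at 8.04 and CCL3L1 at 811 against 3 UMIs (ratio 370, 95% interval 126 to 1797), a near-identical copy of CCL3. Of 18 tumour-associated macrophage genes 15 rose (16 adjusted over the list alone), with C1QA at 3.20, APOE at 9.87 and the lipid receptor gene TREM2 at 356 against 2 UMIs (ratio 244, 95% interval 66.9 to 2019). Of 31 proliferation genes 29 rose (31 adjusted over the list alone), with MKI67 at 116 ± 37.4 against 2.12 ± 0.290 CPM, CENPF at 5.48, TYMS at 5.52 and TOP2A at 5.26. Of 21 immediate early and heat shock genes, which cells can also induce during isolation, 15 rose under both adjustments, with FOS at 1245 ± 137 against 36.8 ± 7.87 CPM, FOSB at 5.46, NR4A1 at 5.33 and ATF3 at 4.31. Camera's adjusted p values were 4.78e-27, 3.01e-17, 8.72e-24 and 2.37e-14, and with an estimated correlation the adjusted p values were 0.0951, 0.308, 0.308 and 0.308. Median mitochondrial shares were 1.11% to 4.59% in the tumour and 2.82% to 6.06% in blood.

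Of 22 hypoxia and glycolysis genes 11 rose and 2 fell (15 and 2 adjusted over the list alone), with VEGFA at 126 ± 16.1 against 1.71 ± 0.425 CPM, SLC2A3 at a log2 fold change of 2.59 and EGLN3 at −2.62. Of 17 TNF response genes 6 rose and 2 fell (8 and 2 adjusted over the list alone), with IER3 at 2.87. Of 17 unfolded protein response genes 11 rose (12 adjusted over the list alone), with HSPA5 at 2.02, SESN2 at 2.88 and SDF2L1 at 1.79. Of 18 scavenging and suppressive myeloid genes 6 rose and 4 fell under both adjustments, with CD163 at 4.71, MSR1 at 5.87 and STAB1 at 6.102, while the mannose receptor gene MRC1 stood at −0.10 (adjusted p = 0.862). Of 22 type I interferon genes 8 rose (10 adjusted over the list alone), with IFI27 at 6.05, IFI6 at 2.35 and IFIT1 at 2.38. The 5 lists had camera adjusted p values of 0.00146, 0.000291, 2.09e-05, 0.0234 and 0.00557, and with an estimated correlation each had an adjusted p = 0.308.

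Of 15 classical blood monocyte genes 6 fell and 1 rose under both adjustments (camera adjusted p = 0.0342, up to 0.180 with a mouse left out, and adjusted p = 0.419 with an estimated correlation). S100A8 (−1.56) fell, as did FCN1 and the scavenger receptor gene CD36, while CD14, the co-receptor for endotoxin, was the member that rose (547 ± 231 against 20.3 ± 16.1 CPM). Interferon gamma genes had 4 of 19 lower and 0 higher under both adjustments (adjusted p = 0.157), among them IDO1 (−4.29) and IRF8 (61.1 ± 7.49 against 391 ± 108 CPM). IRF8 stood at 0.24 (adjusted p = 0.625) when the dendritic-like cells were left out, and IDO1, CLEC9A, CADM1 and DNASE1L3 were then too low to be tested. MHC class II genes had 0 of 13 changed under both adjustments (adjusted p = 0.978), with HLA-DRA at 0.33 and CD74 at 0.40. MHC class I genes had 1 of 14 higher, CALR (1.35), and 1 lower, ERAP2 (−2.12), under both adjustments (adjusted p = 0.978).

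Other genes with 0 UMIs in blood myeloid-like cells were FCGBP (at least 3118-fold higher in the tumour), APOC2 (at least 655-fold), LNCAROD (at least 422-fold), RNASE1 (at least 316-fold), PLEK2 (at least 257-fold) and the growth factor gene AREG (at least 148-fold). SLC16A10 had 4016 against 2 UMIs (ratio 2748, 95% interval 760.1 to 22696) and the macrophage elastase gene MMP12 452 against 1 (ratio 618, 95% interval 110.5 to 24482). Lower in the tumour, among the largest falls at a mean log2 CPM of at least 5, were NEGR1 (−8.70), CADM1 (−7.32), DNASE1L3 (−6.94), AUTS2 (−6.64), CNR2 (−6.51) and SLC24A4 (−6.47), and AUTS2 and SLC24A4 stood at −3.29 and −2.98 in monocyte or macrophage-like cells alone. THRB had 2 against 740 UMIs (ratio 270.4, 95% interval 74.6 to 2237), and the haemoglobin genes HBB and HBD had 1 each against 3224 and 455 (ratios 2356, 95% interval 423 to 93092, and 333, 95% interval 59.4 to 13163). Both haemoglobin genes were present in every blood class examined, so that their blood signal is not particular to myeloid-like cells. The count of changed genes was 4907 without mouse 1 and 1312 without mouse 2, and S100A8 did not pass without mouse 2.

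On myeloid-like cells 6 of 10 tested antibodies passed edgeR's threshold. CD14 rose from 11.6, 16.8 and 8.15 UMIs per cell in blood to 169, 31.5 and 30.02 in the tumour of mice 1, 2 and 3 (log2 fold change 3.01, adjusted p = 0.0307). CD15 stood at 2.97 (adjusted p = 0.00755), CD235a at 1.84 (adjusted p = 0.0172), CD3 at 1.65 (adjusted p = 0.0111), CD8 at −1.17 (adjusted p = 0.0172) and CD11b, with at most 0.123 UMIs per cell, at 3.91 (adjusted p = 0.0338). Without mouse 2 or without mouse 3 the count was 0, and HLA-ABC stood at 0.19 (adjusted p = 0.613). Limma on centred log ratios called 4 antibodies, CD14, CD15, CD235a and CD8. In that test CD3 stood at −0.17 (limma adjusted p = 0.312) and CD11b at 0.10 (limma adjusted p = 0.442). The same limma test also called CD14, CD15 and CD235a higher on T-like cells of the tumour, where edgeR called only CD15 of these. CD8 antibody was lower on those T-like cells too. In the tumour CD15 had 4.12 to 5.42 UMIs per cell on myeloid-like and 3.76 to 4.26 on T-like cells. CD235a had 4.55 to 6.13 and 3.86 to 5.16 in the same order. The CD15 and CD235a signals of the tumour are therefore not particular to myeloid-like cells.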

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

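The items here were listed by rules fixed before the results, and no test was made of them after they were seen. Between CD8 and CD4 T cells, 3 lists differed in their tissue difference by camera with its preset correlation: naive and central memory genes (adjusted p = 2.74e-11), MHC class II genes (adjusted p = 5.69e-06) and interferon gamma genes (adjusted p = 0.0144). None was called with an estimated correlation, and the cause was not tested.

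Hashtags outside the map were counted as well. Hashtag 3, which the map leaves unused, gave 1.29e+06 UMIs in the tumour-cell library, 1.07e+06 in the blood library and 1.19e+06 in the tumour-infiltrating library, with medians of 72, 56 and 48 UMIs per barcode. In blood cells of mouse 3 its median was 277 and in tumour-infiltrating cells of mouse 3 it was 169. Hashtag 8 gave 688 UMIs in the tumour-cell library, of which 547 were in cells of mouse 5. Hashtag 5 gave 4 UMIs in the blood and 78 in the tumour-infiltrating library, and hashtag 6 gave 9 and 137. The source of these signals was not tested.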

How the results depend on the processing

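Of the alternatives below, those added only after the results were seen are all sorted singlets, clusters filled by every mouse, T cell subsets split by UMIs, and monocyte or macrophage-like cells alone. The count of 378 genes changed in tumour cells was 741 with DESeq2, 1712 without a filter on low counts, 246 in sums thinned to the smallest total, 1109 in all sorted singlets and 660 in clusters with at least 20 cells in every mouse. Leaving out a mouse gave 88 to 653, and the fits without mouse 4 or 5 assume that the lone naive sample varies like the others. Without mouse 1 the count was 133, without mouse 2 it was 88, without mouse 3 it was 237 and without mouse 4 it was 653.

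The counts for T-like cells ranged from 1129 to 6855 over fits without a mouse (3039 without mouse 1, 1129 without mouse 2), those for CD8 T cells from 1287 to 3780 (1475 without mouse 1), and those for CD4 T cells from 1483 to 7119 (2124 without mouse 1). In each of these the lowest count came without mouse 2 and the highest without mouse 3. Without a filter on low counts CD8 T cells had 4022. The count for myeloid-like cells ranged from 1312 without mouse 2 to 4907 without mouse 1, with 1898 without mouse 3. For the difference between CD8 and CD4 T cells the count of 0 became 160 with DESeq2, 233 without a filter on low counts and 2 with subsets split by UMIs, and it ranged from 0 to 201 (201 without mouse 3).

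With an estimated correlation camera called 0 lists in tumour cells, 0 in T-like cells, 0 in CD8 T cells, 0 in CD4 T cells, 0 in myeloid-like cells and 0 for the difference between CD8 and CD4 T cells. Fry called 0 lists in tumour cells and 0 for that difference, but 9 of 15 in T-like cells, 11 of 15 in CD8 T cells, 9 of 15 in CD4 T cells and 8 of 13 in myeloid-like cells. IRF8 in myeloid-like cells, at −2.65 in the main setting, turned to 0.24 in monocyte or macrophage-like cells alone, which leave out the dendritic-like cells of the blood.

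Surface proteins changed in tumour cells numbered 1 with limma on centred log ratios against 0 with edgeR, and 0 to 3 over fits without a mouse (3 without mouse 3, 1 without mouse 4). In T-like cells the 3 proteins became 6 with library size scaling only and 1 in every fit without a mouse. Without the mouse block 1 protein (CD8) remained, and in the same cells IFI44 and IDO1 no longer passed (adjusted p = 0.0673 and 0.0563). Dropping the block changed no other call for the genes named here. In myeloid-like cells the 6 proteins became 4 with limma on centred log ratios, 0 without mouse 2 or mouse 3 and 7 without mouse 1. The share difference of myeloid-like cells ranged from −1.85 without mouse 3 to 2.16 points without mouse 1. The cause of these shifts was not tested. Tests of B-like and NK-like cells were not run, because fewer than 20 such cells per mouse came from the tumour, and an antibody class of B cells was not formed. Keeping the cells that Scrublet marked left the data nearly unchanged.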

Other observations

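The sorted tumour cells included a cluster of 563 cells with fibroblast or pericyte markers, 538 of them from humanized and 25 from naive mice. It made up 12.8% ± 2.31 of the cells of humanized mice (n = 3) and 0.509% ± 0.497 of those of naive mice (n = 2), with an exact permutation p = 0.1, the smallest possible. COL3A1, a fibrillar collagen gene, stood at 444 CPM in this cluster and at 2.43 CPM in glioma-like cells, COL1A2 at 397 and 3.57 CPM, and the pericyte receptor gene PDGFRB at 41.7 and 22.96 CPM. The glioma genes SOX2 (82.9 against 308 CPM) and PTPRZ1 (165 against 1087 CPM) were lower, and these genes were picked after their values were seen. Whether these are mouse stromal cells whose reads matched the human reference, or tumour cells in another state, was not tested, although the sort for EGFP selects against mouse cells.

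Among the tests in this section, the 3 on the CD8 antibody and the settings outside the hypoxia-led cluster and in clusters filled by every mouse were chosen only after those results were seen. The higher type I interferon genes of tumour cells in humanized mice could come from RNA of human immune cells in the same droplets. The risen genes would then need a median of at least 18.8% immune RNA, while the medians for T cell and monocyte or macrophage markers were 0%, 0% and 0.0111%, which speaks against it. Of the 16 list genes that rose, 13 still rose in sums thinned to the smallest total, so that the totals of the sums do not explain these 13. Thinning the sums does not make the UMIs per cell equal, which were lowest in mouse 1 (median 5626). In clusters filled by every mouse 15 of 20 list genes still rose, but these include the interferon-led cluster 11, so that a difference in tumour cell states stays open, as does chance among 2 naive mice. Exposure to interferon made by human T or myeloid cells is a hypothesis beside these. Tumours in humanized mice given an antibody that blocks the type I interferon receptor would test it for type I interferon only. Exposure to interferon gamma would stay untested.

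The lower hypoxia genes could come from a cluster led by such genes that mouse 4 mostly holds, yet outside it the list's median was still −0.81. Cluster 3, with VEGFA among its leading genes and nearly all of its cells from mice 4 and 5, was kept there, and in clusters filled by every mouse the median was −0.58 with 6 of 27 genes lower, so that clusters held by naive mice may carry part of the fall. The totals of the sums explain little, because 12 of the 14 fallen genes still fell in thinned sums. Here too the UMIs per cell were not made equal. A tumour size or perfusion that differs between hosts could also lower VEGFA and BNIP3, whereas with 2 naive mice such a difference may be a matter of these animals. Pimonidazole staining of size-matched tumours in more naive mice would part these.

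The lower CD8 antibody signal on T-like cells of the tumour could reflect a weaker antibody signal in the library, fewer CD8 T cells or a loss of this signal on any cell. CD3 antibody UMIs were at least 1.18 times as high in the tumour as in blood, and in cells with CD8A or CD8B UMIs and no CD4 UMIs the CD8 antibody median was at most 0.0284 of that in blood. Both speak against the first and the next explanation. In CD8-type clusters made up of over 90% blood cells, the 97 tumour cells had a median of 7 UMIs against 828 in blood, a ratio of 0.00845, which fits a loss whatever the cell, for example an epitope cut or blocked during isolation. Blood cells taken through the tumour digestion and stained again would test this.

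For T-like, CD8 T, CD4 T and myeloid-like cells, 1 of 10 splits of the 6 sums gave as many genes as the real split (4849, 2592, 4738 and 2827), and the highest other split gave 0. For the difference between CD8 and CD4 T cells 10 of 10 splits gave as many as the real 0. With 10 splits such a share cannot go under 0.05. Every other split put tumour and blood sums in both groups, and tissue was not in the model. The tissue difference then entered the spread of those fits, which leaves little room for calls. A real count of 0 is matched by any split. These counts therefore cannot decide whether the changes arose by chance.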
